A study of Mus musculus with 2 samples.

How the data were processed

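Chromatin accessibility was measured by ATAC-seq, in which Tn5 transposase inserts sequencing adapters into open DNA. The cells were wild-type C57Bl/6J mouse neural stem and progenitor cells from the wall of the lateral ventricle, kept for 48 h as floating neurospheres (adult neurosphere cells) with EGF and FGF2. Per the labels, 2 biological replicates were made, with 10000 and 12000 cells put into the transposition. There was 1 group and no control or treated group, so no group was compared with another.

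The authors deposited 2 kinds of file. The first is a list of 81141 peak positions without any value, called the longer peak list here. The second is a table of 41836 peaks with a normalized value per library and the nearest gene, called the quantified peaks here. In the deposited table the values are treated as a score: they are read counts per peak that the authors normalized and rounded to whole numbers, per the file headers and the values. Per the submitters' processing notes, reads were handled with Trimmomatic 0.39, STAR 2.7.10a, Picard 3.0.0, featureCounts (version not given in the sources used here) and DESeq2 1.36.0 on the mouse build mm10. The sources used here do not give the role and order of these tools, the peak caller or whether the libraries were pooled for it. Nor do they give how the quantified peaks relate to the longer list, or any shift of the reads for the transposase. The value columns are named Unsort with a number, not by the sample titles, and the meaning of that word is not given in the sources used here. The columns were taken as the replicates of the group and are called library 1 and library 2. All values rest on this reading. Which of them received 10000 or 12000 cells was not used.

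Depth was read from the steps of the values. In library 2 regular gaps between the whole numbers gave a worth of 1.56 per read, and in library 1 the number of times each value occurred gave 0.642 per read. Dividing the summed values by these steps gave an estimated 3186190 reads in peaks for library 1 and 1500301 for library 2. At the median peak this is an estimated 46.7 reads in library 1 and 21.2 in library 2, which gives a counting error of 14.6% and 21.7%. A simulation with these depths gave the agreement expected from counting error alone. Because the raw counts could not be recovered for library 1, where steps are smaller than the rounding, no count model was used.

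Gene names and gene types came from the authors' annotation, which assigns at most 1 gene to a peak, up to 5830 bp from the peak centre to the start site. It was joined to a RefSeq table of the assembly GRCm38, the same assembly as mm10, with gene extents but without strand or transcripts. Of the 11174 protein-coding genes in the authors' annotation, 11119 (99.5%) matched a RefSeq symbol, by symbol, synonym or position. A promoter peak is a quantified peak whose centre lies within 1 kb of the start site of its assigned gene. Peaks of the longer list have no assigned gene, so they were counted within 1 kb of either end of a gene. This can miss start sites inside a gene. Of 255 list genes with a promoter peak, 13 had no quantified peak at either end. Other peaks whose centre lies in a RefSeq protein-coding gene were classed as gene body and the rest as intergenic. Exons, introns and UTRs were not told apart, and no genome sequence was used here, so the planned motif counts were not run. Distal peaks (all that are not promoter peaks) were assigned to every protein-coding gene that holds the peak centre, or else to the nearest one within 100 kb. This replaced the planned nearest start site, since start sites of all genes were not in the table used here. Positions are those of the authors' table in mm10.

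A set of 26 gene lists (590 entries, 558 genes) was fixed before the data were examined, for stem cell states, other cell types of the ventricle wall and brain, regional transcription factors, signalling pathways and tissues outside the brain. For each list the number of members with a promoter peak was set against all other RefSeq protein-coding genes with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over the 26 lists. Shares carry 95% Clopper-Pearson intervals. Because genes are not independent replicates, these p-values describe overlap within 1 peak set. In addition 6 pairs of lists were compared with each other by Fisher's exact test, adjusted over these 6 pairs only. The pairs were not part of the plan made before the data were examined. For promoter signal, the median over members of log2 (mean value + 1) of the strongest promoter peak was placed among 10000 random lists of the same size. For distal peaks, the mean number per gene was placed among 10000 random lists, and again among lists matched on gene length in 20 bins. A list was called when its percentile lay outside 2.5 to 97.5. By chance 1.3 of 26 lists would. The library difference is log2 (library 2 + 1) minus log2 (library 1 + 1). Regional medians of that difference were taken over 5-Mb windows with at least 20 non-promoter peaks. Domains join quantified peaks within 12.5 kb and are ranked by their summed mean value. A mean ± SD is over the 2 libraries.

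Genes are named by a rule fixed before the data were examined. It takes from each list up to 4 members with the strongest promoter peaks and the first 4 without one, all TALE homeodomain members, the 20 highest peaks, the genes nearest to the top 20 domains, the 10 genes with the most distal peaks, and the 10 largest library differences among peaks at or above the median value of 32.5. The list tests were tested on simulated data for 21631 genes. The promoter test called 116 of 120 lists planted at 90 percent and 120 of 120 planted at 5 percent, and 3 of 280 lists at background. The distal percentile called 18 of 18 lists planted 3 peaks higher per gene and 0 of 42 at background. Simulated lists held random genes, and simulated distal counts did not depend on gene length, unlike the real counts. The simulations therefore do not give the rate of false calls for real lists, nor the power for smaller differences. Alternatives covered the promoter window, the low peaks, each library by itself, the background genes, the assignment of peaks, gene length, pseudocount, scaling and joining distance, and the longer peak list. Analyses were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.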

Results

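Open chromatin was profiled by ATAC-seq in wild-type adult mouse neural stem and progenitor cells from the ventricular-subventricular zone (V-SVZ, the stem cell niche beside the lateral ventricle), grown as neurospheres. There were 2 libraries of 1 group and no second condition, so the questions are which genes and regions were open and how closely the libraries matched. The authors quantified 41836 peaks with a median width of 354 bp, covering 17.4 Mb of mm10. Summed normalized values were 2046171 in library 1 and 2336269 in library 2, which correspond to an estimated 3186190 and 1500301 reads in peaks. The median peak had a normalized value of 30 in library 1 and 33 in library 2. Intervals and errors below cover counting or the spread of these 2 libraries only.

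Promoters of genes for proliferation, growth factor response, developmental signalling and neuroblasts were open more often than those of other genes. So were those of housekeeping genes (75%) and chromatin regulators (81.8%), so the excess was not particular to these functions. No list was tested against housekeeping genes. The housekeeping genes Tbp, Ywhaz, Eef1a1 and Eef2 had no assigned promoter peak. With a quantified peak at either gene end, the housekeeping share was 24 of 28 (85.7%), against 51.5% of other genes. Of 303 list genes without a promoter peak, 33 had a quantified peak at a gene end. A missing promoter peak therefore need not mean a closed promoter. Of the 30 cell cycle and DNA replication genes, 26 had a promoter peak (86.7%, 95% interval 69.3 to 96.2), against 46.2% of other protein-coding genes (Fisher's exact test, adjusted p = 0.000102). Mcm4, a subunit of the replicative helicase, had the strongest promoter peak of this list, at a normalized value of 410 ± 63.6 (SD, n = 2). Mcm3, of the same helicase, stood at 246 ± 6.36 and Ccna2, cyclin A2, at 231 ± 26.2. Of the 28 EGF, FGF and MAPK response genes, 23 had a promoter peak (82.1%, adjusted p = 0.000637 by Fisher's exact test). These included Jun, an AP-1 subunit, at 341 ± 36.1, the ERK phosphatase Dusp6 at 263 ± 29.0, the ETS factor Etv5 at 229 ± 37.5 and the feedback inhibitor Spry2 at 215 ± 15.6. Erbb2, Erbb4, Fgfr1 and Fgfr3 had no assigned promoter peak. All 4 had a peak of the longer list within 1 kb of a gene end, and Fgfr1 also a quantified one. The BMP, WNT and SHH pathway list had 22 of 27 genes with a promoter peak (81.5%, adjusted p = 0.000973 by Fisher's exact test), led by the WNT receptor Fzd1 at 214 ± 9.19 and the hedgehog effector Gli3 at 147 ± 0.707. Bmp4, Smad6 and Lef1 had no promoter peak, nor a peak of the longer list at a gene end. Ctnnb1 had no assigned promoter peak but a quantified peak at a gene end.

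Among lists for stages of the V-SVZ lineage, 25 of 31 neuroblast and olfactory bulb interneuron genes had a promoter peak (80.6%, 95% interval 62.5 to 92.5, adjusted p = 0.00056 by Fisher's exact test). Sox11, a SoxC factor of immature neurons, had a promoter value of 190 ± 44.5, Cd24a 130 ± 7.07 and Sox4 118 ± 2.83 (SD, n = 2). Th, the rate-limiting enzyme of dopamine synthesis, and Pax6 had no promoter peak, nor a peak of the longer list at a gene end. Gad1 and Tshz1, without an assigned promoter peak, had a quantified peak at a gene end. The activated neural stem cell (NSC) and transit-amplifying progenitor list had 19 of 27 genes with a promoter peak (70.4%, 95% interval 49.8 to 86.2, adjusted p = 0.0324 by Fisher's exact test). Its strongest were Vim, an intermediate filament gene, at 195 ± 15.6, Sox1 at 142 ± 71.4, the EGF receptor gene Egfr at 138 ± 1.41 and the matrix gene Tnc at 138 ± 13.4. Nes, Ccnd1 and Ccnd2 had no promoter peak among the quantified peaks but a peak of the longer list at a gene end, and Dll3 had neither. The quiescent NSC and astrocyte list had 15 of 28 (53.6%, adjusted p = 0.537), with Hey1, a Notch target, at 280 ± 15.6 and Id2, a target of BMP signalling, at 176 ± 32.5. Of the first 4 members without a promoter peak, Gfap, Aqp4 and Gja1 had none at a gene end in the longer list either, while Aldoc had a quantified peak at a gene end. The activated list did not differ from the quiescent list (18 of 26 against 14 of 27 after leaving out the 1 shared gene, adjusted p = 0.264 over 6 unplanned pairs of lists, Fisher's exact test). The call of the activated list was lost with a 500 bp window (59.3%, adjusted p = 0.182), a 2.5 kb window (still 70.4%, adjusted p = 0.0563), only peaks at or above the median value (59.3%, adjusted p = 0.0647) and a background without olfactory and vomeronasal receptor genes (still 70.4%, adjusted p = 0.0557). Its adjusted p ranged from 9.97e-08 to 0.182 over 10 alternatives (Fisher's exact test).

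**Figure D1:**
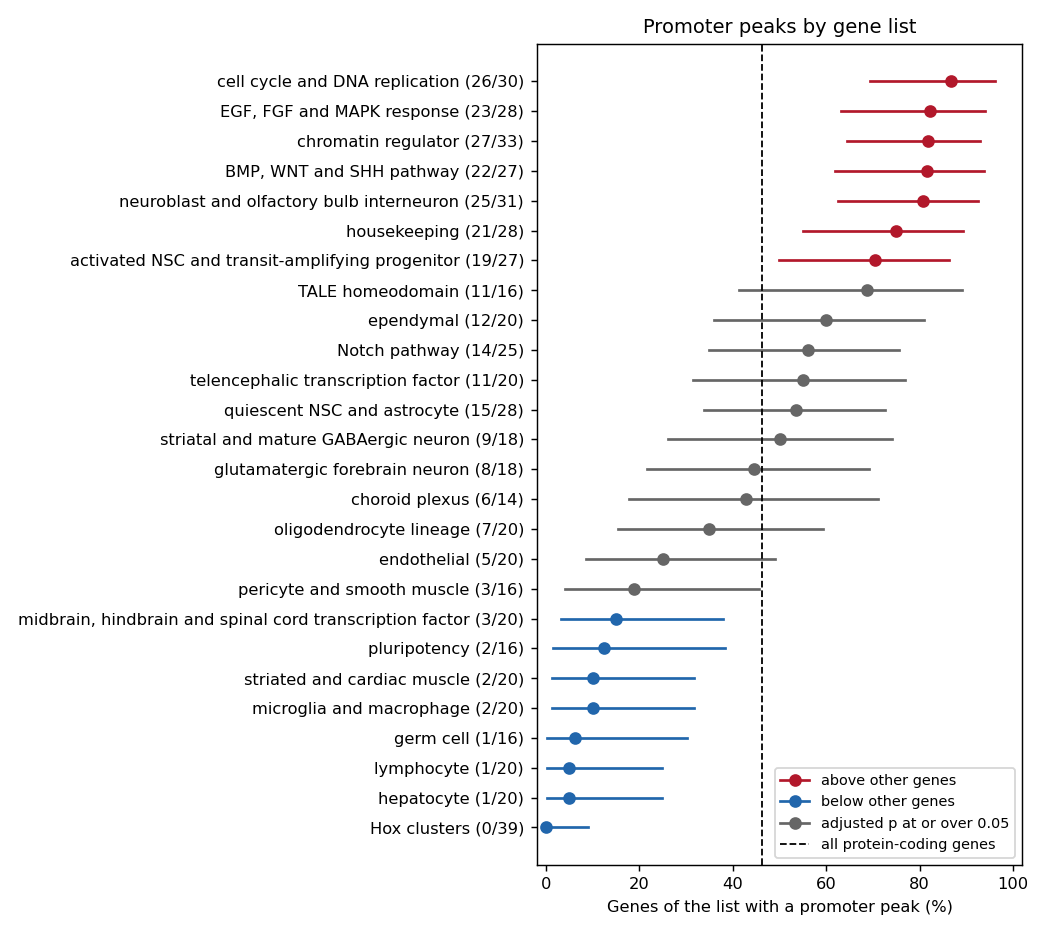
Share of each gene list with a promoter peak (x axis, percent), with the 95% Clopper-Pearson interval as a line and the number of genes in brackets. The dashed line marks all protein-coding genes (46.3%). Lists in red lie above other genes and those in blue below at an adjusted p under 0.05, from 26 of 30 for cell cycle genes to 0 of 39 for Hox genes.

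The TALE homeodomain genes, which encode cofactors such as MEIS and PBX proteins, had a promoter peak at 11 of 16 members (68.8%, 95% interval 41.3 to 89.0, adjusted p = 0.119 by Fisher's exact test). Pbx4 had 181 ± 49.5, Pknox1 180 ± 132, Pbx1 120 ± 31.1, Pknox2 118 ± 70.0, Meis3 114 ± 75.7 and Pbx3 95.5 ± 70.0 (normalized values, SD, n = 2). Lower values were found for Tgif1 at 66 ± 14.1, Mkx at 61.5 ± 7.78, Irx2 at 61.5 ± 12.0, Meis2 at 49.5 ± 16.3 and Meis1 at 44 ± 1.41. The Meis2 promoter peak lies at chromosome 2, 116065677 to 116065938, 31 bp from the start site, and that of Meis1 at chromosome 11, 19018917 to 19019150, 49 bp from it. Pbx2, Tgif2, Irx1, Irx3 and Irx5 had no promoter peak, and the first 4 of these had a peak of the longer list at a gene end. Pbx1 had 11 distal peaks, Meis1 10, Pknox2 8, and Meis2 and Pbx3 had 5 each. With only peaks at or above the median value the list was above other genes (adjusted p = 0.0362), and over 10 alternatives its adjusted p ranged from 0.00012 to 0.849 (Fisher's exact test).

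**Figure D2:**
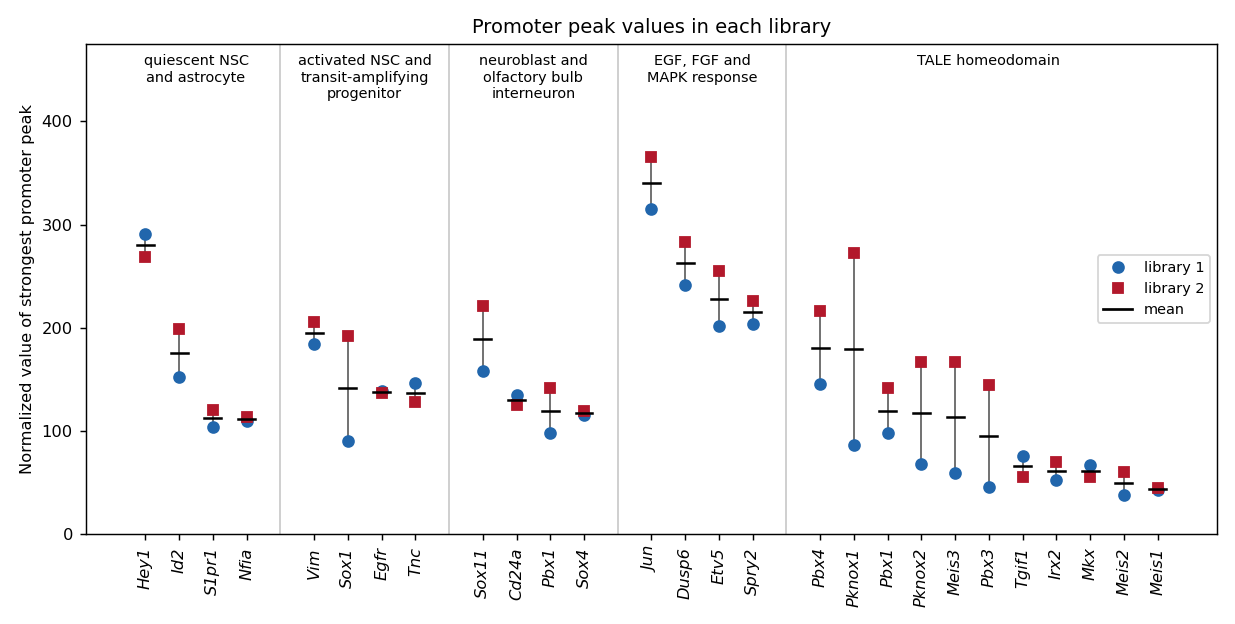
Normalized value of the strongest promoter peak (y axis) in library 1 (blue circle) and library 2 (red square) with their mean (black line), for the 4 strongest members of 4 lists and the 11 TALE homeodomain genes with a promoter peak. Egfr stood at 139 and 137 in the libraries, while Pknox1 stood at 87 and 273.

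Promoter peaks were rare at Hox genes and at genes of other tissues. None of the 39 Hox genes, which set position along the hindbrain and spinal cord, had a promoter peak (95% interval up to 9.03%, adjusted p = 8.7e-10 by Fisher's exact test). Of 20 microglia and macrophage genes 2 had one, P2ry12 at 27 ± 1.41 and Irf8 at 25 ± 17.0 (10.0%, adjusted p = 0.00249 by Fisher's exact test). Aif1, Cx3cr1, Csf1r and Tmem119 had none, nor a peak of the longer list at a gene end. The only hepatocyte gene was Ttr, also a choroid plexus gene, at 37.5 ± 17.7 (1 of 20, adjusted p = 0.00056 by Fisher's exact test). Tcf7 was the only lymphocyte gene, at 17 ± 7.07 (1 of 20, adjusted p = 0.00056), and Dazl the only germ cell gene, at 63.5 ± 12.0 (1 of 16, adjusted p = 0.00231, Fisher's exact tests). The striated and cardiac muscle list had Mylpf at 201 ± 141 and Ckm at 19 ± 17.0 (2 of 20, adjusted p = 0.00249), and the pluripotency list Lin28b at 93 ± 4.24 and Tfcp2l1 at 13 and 12 in the libraries (2 of 16, adjusted p = 0.0179, Fisher's exact tests), without Pou5f1 or Nanog. Among transcription factors of the midbrain, hindbrain and spinal cord, 3 of 20 had a promoter peak (Mafb at 112 ± 40.3, Atoh1 at 70 ± 11.3 and Ptf1a at 45 ± 1.41; adjusted p = 0.0115 by Fisher's exact test). For telencephalic transcription factors it was 11 of 20, with Dlx2 at 74.5 ± 26.2, Arx at 72.5 ± 23.3 and Sp8 at 65 ± 7.07. This list did not differ from other genes (adjusted p = 0.57) but was above the midbrain, hindbrain and spinal cord list (adjusted p = 0.0374 over 6 unplanned pairs, Fisher's exact tests). In the longer peak list the midbrain, hindbrain and spinal cord list was not below other genes (9 of 20, adjusted p = 0.315) nor apart from the telencephalic one (adjusted p = 0.105, Fisher's exact tests). Its call was kept in 5 of 10 alternatives and lost also with a 2.5 kb window (5 of 20, adjusted p = 0.064) and upper peaks (3 of 20, adjusted p = 0.054), with a range from 0.00559 to 0.813 (Fisher's exact tests). Against all RefSeq genes, of which 20.2% had a promoter peak, each of the 8 low lists but the Hox genes lost its call, with adjusted p from 0.145 to 0.813 (Fisher's exact tests). The pluripotency call was also lost when peaks in regions with a library difference over 1 were left out (adjusted p = 0.168, Fisher's exact test). Genes in those regions then counted as without a promoter peak, so this loss does not test the call for genes outside them.

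The remaining cell type lists were not called against other genes with the settings chosen beforehand, and some were called under alternatives. The oligodendrocyte lineage list had 7 of 20 promoters open (adjusted p = 0.486), among them the galactolipid synthesis gene Ugt8a at 275 ± 23.3, Olig1 at 69.5 ± 3.54 and Olig2 at 35 ± 2.83, but not Sox10, Pdgfra or Cspg4. Neuroblast genes were open more often than oligodendrocyte lineage genes (adjusted p = 0.00736) and quiescent NSC and astrocyte genes more often than microglia genes (adjusted p = 0.00736, Fisher's exact tests over 6 unplanned pairs). The other 3 pairs gave adjusted p of 0.0741 for neuroblast against quiescent genes, 0.153 for oligodendrocyte lineage against microglia genes (0.045 in the longer peak list, 12 of 20 against 4 of 20), and the 0.264 given above (Fisher's exact tests). The ependymal list had 12 of 20 (adjusted p = 0.361), led by the ciliary regulators Rfx3 at 237 ± 33.2 and Ccno at 228 ± 37.5. Endothelial genes had 5 of 20 (adjusted p = 0.11), with Kdr at 84 ± 21.2, and pericyte and smooth muscle genes 3 of 16 (adjusted p = 0.0674), with Kcnj8 at 49 ± 18.4. The endothelial list was below other genes in 3 of 10 alternatives (adjusted p from 0.00206 to 0.656 over the 10) and the pericyte list in 6 of 10, including each library alone (adjusted p from 0.017 to 1, Fisher's exact tests). The choroid plexus list had 6 of 14 (adjusted p = 1), the glutamatergic forebrain neuron list 8 of 18 (adjusted p = 1) with Syt1 at 221 ± 55.9, the striatal and mature GABAergic neuron list 9 of 18 (adjusted p = 0.884) with Foxp2 at 73.5 ± 16.3, and the Notch pathway list 14 of 25 (adjusted p = 0.523) with Hey2 at 323 ± 37.5 (Fisher's exact tests). In the longer peak list the Notch list was above other genes (21 of 25, adjusted p = 0.0151, range over 10 alternatives 0.000254 to 1). Against all RefSeq genes the Notch, quiescent NSC, ependymal, striatal, telencephalic, TALE and glutamatergic lists were called higher, with adjusted p from 0.00012 to 0.0305 (Fisher's exact tests). In lists outside any lineage, chromatin regulators had 27 of 33 (81.8%, adjusted p = 0.000295, Fisher's exact test), led by the histone demethylase gene Kdm6a at 493 ± 26.2. Housekeeping genes had 21 of 28 (adjusted p = 0.00778, range over 10 alternatives 3.11e-09 to 0.0876, Fisher's exact tests). The highest of these came from leaving out peaks in regions with a library difference over 1 (53.6%, adjusted p = 0.0876, Fisher's exact test). Genes there then counted as without a promoter peak, so 53.6% is not the share of genes outside those regions.

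Where a promoter was open, its signal was low for 4 lists. The median log2 value of the strongest promoter peak was 4.68 for 6 choroid plexus genes (percentile 0.15 of random lists), 4.91 for 9 striatal and mature GABAergic neuron genes (percentile 0.185), 4.91 for 7 oligodendrocyte lineage genes (percentile 0.41) and 4.78 for 5 endothelial genes (percentile 0.84). Random lists of these sizes had medians near 6.29. The lists of cell cycle genes (6.45, percentile 71.2), EGF, FGF and MAPK response genes (6.64, percentile 89.6), chromatin regulators (6.67, percentile 93.1) and TALE genes (6.59, percentile 76.8) lay within the random range. With the main settings, as in the values above, no list lay above it, of 19 lists with at least 3 members. The EGF, FGF and MAPK list did in 4 of 6 alternatives (2.5 kb window 99.6, upper peaks 97.9, library 1 alone 99.2, library 2 alone 97.9), chromatin regulators in library 2 alone (97.8) and cell cycle genes per kb of peak (97.7). From library 1 alone the oligodendrocyte lineage, endothelial and striatal lists were no longer below it (percentiles 3.64, 15.3 and 11.9), nor were oligodendrocyte lineage genes with upper peaks (28.0) or endothelial genes with a 500 bp window (4.13), while glutamatergic neuron genes were below it from library 1 alone (2.19) and with upper peaks (0.86). From library 2 alone 8 lists were called in place of 4, and the activated NSC (percentile 0.48) and telencephalic transcription factor lists (percentile 0.93) were then below it too. Per kb of peak the BMP, WNT and SHH list (percentile 2.12) and the pericyte and smooth muscle list (percentile 2.435) were below it.

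Among the 26 lists, distal peaks were most numerous per gene in the neuroblast list. These are all peaks without an assigned start site within 1 kb. They can include peaks at a gene end that the authors' annotation left unassigned. The 31 neuroblast and olfactory bulb interneuron genes had a mean of 4.77 distal peaks per gene, against 1.05 for all protein-coding genes, above all 10000 random lists, and against a median of 2.13 for lists matched on gene length. Robo2, an axon guidance receptor gene, had 31 and Nrxn3 15 of these, named after their values were seen. The BMP, WNT and SHH pathway list had 3.37 (percentile 99.9), with 16 at Gli3, the quiescent NSC and astrocyte list 3.25 (percentile 99.9), with 17 at Nfia, and the Notch pathway list 2.48 (percentile 98.9). Also above the random range were striatal (3.00, percentile 99.1), telencephalic transcription factor (percentile 98.7), EGF, FGF and MAPK (2.25, percentile 98.0) and activated NSC genes (2.22, percentile 97.7). The glutamatergic neuron list (3.56, percentile 99.8) and the TALE list (3.06, percentile 99.0) were above it too, but not against genes of the same length (percentiles 93.1 and 79.1). Hox (0.0513), germ cell (0.125), microglia and macrophage (0.15) and muscle genes (0.25) lay below the random range. The neuroblast, BMP, WNT and SHH, quiescent NSC, Notch and Hox calls held under all 9 alternatives, and each other call was lost in at least 1. The striatal (percentile 96.6), telencephalic (92.4), EGF, FGF and MAPK (93.7) and activated NSC calls (86.7) were lost with another assignment of peaks. It took only the gene body and 10 kb around it. Across genes the number of distal peaks rose with gene length (Spearman rho 0.49, with genes not independent replicates), and 13683 genes (63.3%) had none. The genes with the most were all long, from 1060 to 2271 kb: Dlg2 (45 in 1973 kb), Macrod2 (43), Cntnap2 (41), Ptprd (39), Pde4d (38), Lsamp (36), Tenm3 and Nrxn1 (34 each), Fhit (33) and Tenm2 (32).

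**Figure D3:**
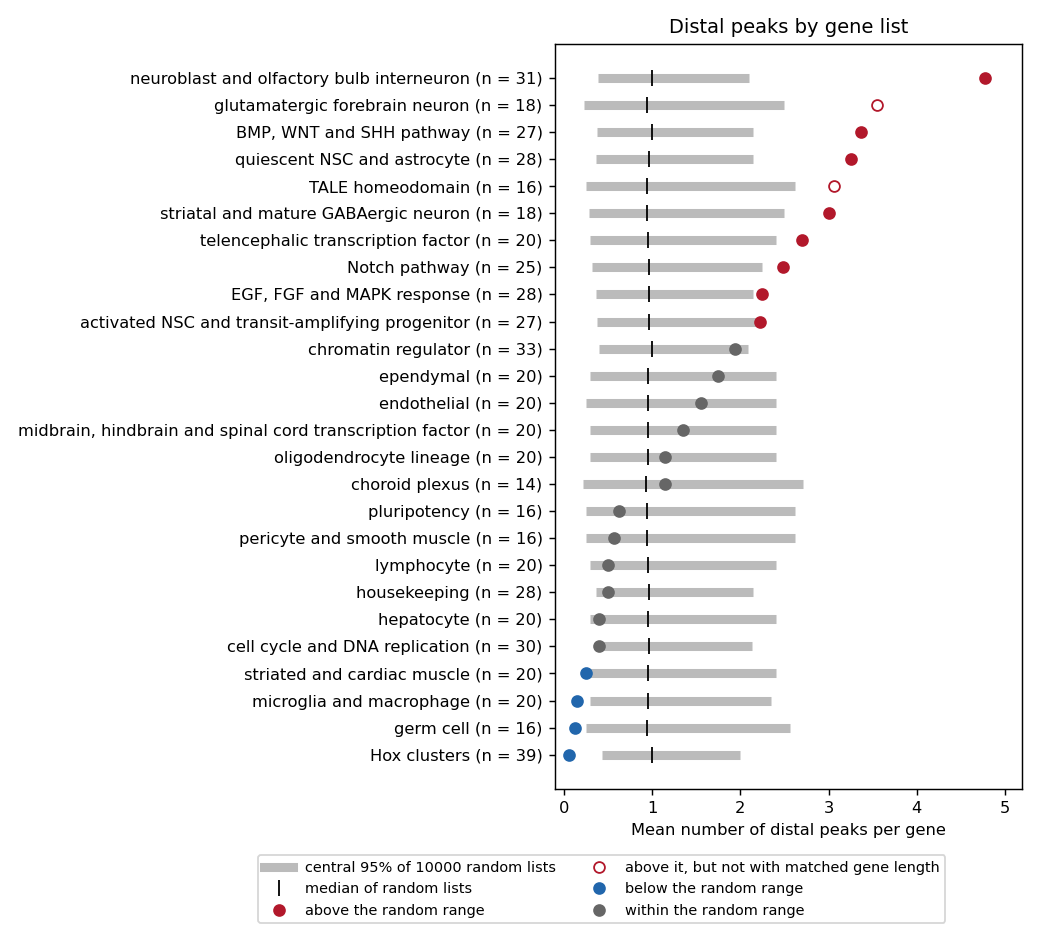
Mean number of distal peaks per gene for each gene list (x axis, points), with the central 95% of 10000 random lists of the same size as a grey bar and their median as a tick. The neuroblast list lies highest at 4.77 and the Hox list lowest at 0.0513. Open points (glutamatergic neuron and TALE lists) fall within the range of genes matched on length.

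The highest single peaks were mainly promoters, 18 of the top 20. Pdcd10 (chromosome 3, 75556512 to 75557736) had 804 ± 120, Evi5l 758 ± 281, the zinc finger gene Sp4 757 ± 96.9, and Zbtb20, a transcription factor gene, 744 ± 0.707 (normalized values, SD, n = 2). Khsrp had 742 ± 375, Garem1 704 ± 26.9, Fam76b 670 ± 83.4, Aasdhppt 658 ± 58.7, Zfp78 654 ± 352 and Pcmtd1 628 ± 6.36. Gpr108, Rap2a, Ppp2r1a, Nmt2, Eny2, Pja2 and Lnpep and a gene without a symbol near Zfp958 completed the promoters, between 599 and 766. The names follow the authors' assignment of 1 gene per peak. Some of these peaks also lay at another gene: Serpini1 for Pdcd10, Cep57 for Fam76b, Kbtbd3 for Aasdhppt, Trip10 for Gpr108 and Nudcd1 for Eny2. The other 2 of the top 20 were a peak without an assigned gene at chromosome 9, 124422932 to 124425444, at 806 ± 400, and one in Crlf2, 1214 bp from its start site, at 724 ± 422. They stood at 523 and 1088, and at 425 and 1022, in libraries 1 and 2. The first was the longest of all quantified peaks, at 2512 bp. No filter for repeated sequence was applied here, and unique mapping of reads at these peaks was not tested. When neighbouring peaks were joined, the highest summed value came from a histone gene cluster on chromosome 13, 23516991 to 23586116, with 18 peaks over 15 histone genes including H4c8 (1347 ± 596). Histone clusters at H2ac12 (670 ± 253) and H1f2 (655 ± 291) on the same chromosome were also among the top 20 of 32639 domains. The domain of highest summed value without a protein-coding gene lay at chromosome 13, 83715060 to 83750307, with 10 peaks and 818 ± 46.0. Mef2c was its nearest protein-coding gene, at 47981 bp. Only protein-coding genes were counted for domains, so a non-coding gene may lie within it, and a link to Mef2c was not tested. Trim28, a corepressor gene, lay in a domain of 5 peaks on chromosome 7 (866 ± 482), and others lay at the imprinted gene Peg3 (710 ± 308), Cic (695 ± 448), Zfp324 (675 ± 216) and Zdhhc5 (656 ± 200). Of the top 20 domains 9 were single peaks, and 7 stayed in the top 20 when values were taken per kb of peak.

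Of all quantified peaks, 11701 (28.0%, 95% interval 27.5 to 28.4) were promoter peaks, 13770 (32.9%) lay elsewhere in gene bodies and 16365 (39.1%) were intergenic. A promoter peak was present at 10005 of 21631 protein-coding genes (46.3%). Promoter peaks had a median value of 70 and gene body peaks 26.5. Promoters took 43.3% of the signal in library 1 and 53.9% in library 2 (48.6% ± 7.55, SD, n = 2). With only peaks at or above the median value, 44.7% were promoter peaks. Nearly all quantified peaks, 41753 (99.8%), overlapped the longer list of 81141 peaks by at least 1 bp. The 39725 peaks of that list without a quantified peak were narrower (median 285 bp against 589 bp) and less often within 1 kb of a gene end (5.37% against 25.1%).

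Across peaks, which are not independent replicates, Pearson's r of log2 values was 0.721 and Spearman's rho 0.721, and 67.7% of peaks were within 2-fold. Counting error alone gave r = 0.946 and 96.8% in a simulation, which leaves out any difference between separate samples. The largest differences among peaks at or above the median value were at the promoters of Dvl2 (4 in library 1, 90 in library 2), Smim12 (8 and 93) and Rpl23 (10 and 101), 1230 bp from the start site of Ppp1r9b (6 and 72) and in Igsf21 (5 and 61). The other 5 of the 10 largest were intergenic peaks higher in library 1, the nearest genes being Prkcq, Mdfic, Neil3, Arl4a and Cog6, with 64 to 89 in library 1 and 5 to 8 in library 2. By chromosome the median difference (library 2 over library 1, log2) was 0.90 on chromosome 11, 0.53 on chromosome 7 and 0.40 on chromosome 9, and lowest on chromosome 3 (-0.29) and chromosome 10 (-0.29). Over 498 windows of 5 Mb the medians of non-promoter peaks had an SD of 0.65, from -1.13 to 2.26, and rose with the number of protein-coding genes in the window (Spearman rho 0.74, Pearson's r 0.777; within chromosomes rho 0.754; none of 488 circular shifts along the genome reached it). Windows are not independent replicates. Centred on the median of its window, r across peaks was 0.834.

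**Figure D4:**
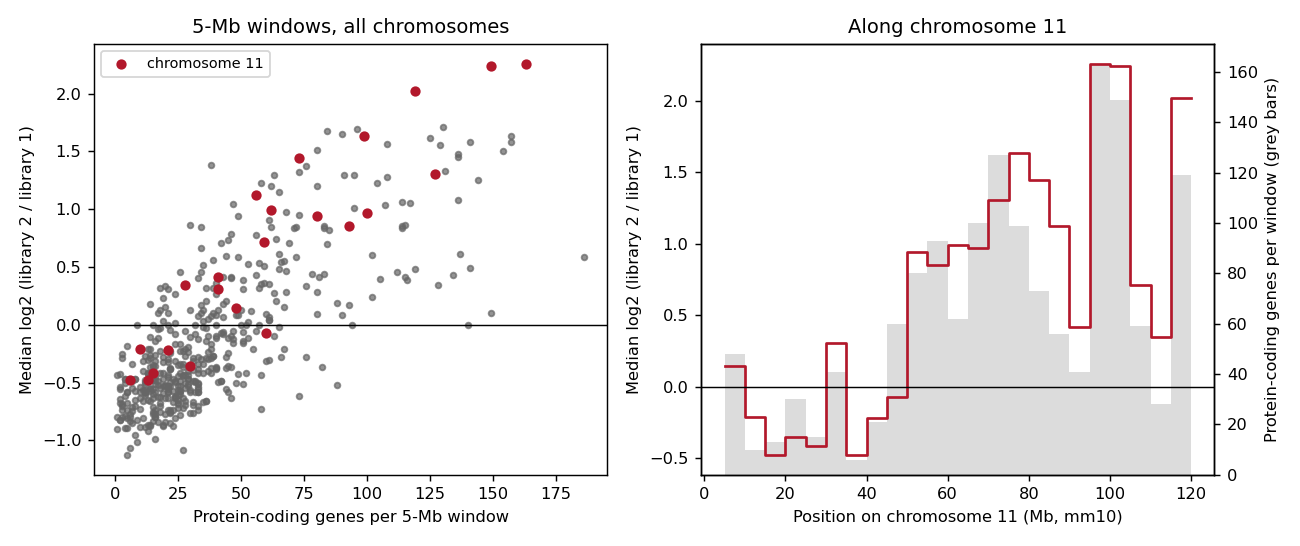
Median log2 ratio of library 2 to library 1 over non-promoter peaks in 5-Mb windows (y axis), against the number of protein-coding genes per window (left, all chromosomes, chromosome 11 in red) and along chromosome 11 in Mb of mm10 (right, line, with gene numbers as grey bars on the right axis). On chromosome 11 the median ran from -0.48 to 2.26.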

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

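The longer peak list, peaks at either gene end, the background without olfactory receptors, the regional centring and the regional exclusion were chosen after seeing the data; the other alternatives were planned. Of 260 recomputed promoter comparisons of lists, 225 gave the same verdict, 17 gained and 17 lost a call, and 1 turned: glutamatergic neuron genes (44.4%) were called above all RefSeq genes, whose lower share causes this. Of 234 distal comparisons 211 were the same, 4 gained and 19 lost a call, and of 108 signal comparisons 91, 12 and 5. The cell cycle, neuroblast, EGF, FGF and MAPK, BMP, WNT and SHH, chromatin and Hox promoter calls held under all 10 alternatives. With peaks in regions with a library difference over 1 left out, housekeeping (53.6%, adjusted p = 0.0876), pluripotency (2 of 16, adjusted p = 0.168) and midbrain, hindbrain and spinal cord genes (3 of 20, adjusted p = 0.168) lost theirs (Fisher's exact test). Genes in those regions stayed in the counts as genes without a promoter peak. These values are thus not shares of the genes outside the regions, and the losses do not test the calls for those genes. Called signal lists were 4, with 7 when values were taken per kb and 3 to 8 when a library was left out, 8 being without library 1. Peaks numbered 21004 at or above the median value and 81141 in the longer list. Promoters made up 24.7% (500 bp), 32.5% (2.5 kb), 44.7% (upper peaks) and 28.6 to 31.9% (leaving out a library). Agreement was r = 0.713 (pseudocount 0.5), 0.746 (pseudocount 5), 0.531 (upper peaks), 0.649 (distal), 0.798 (promoter) and 0.834 (centred by region). Of the top 20 domains 12 stayed when joined over 5 kb, 11 as single peaks, 7 per kb and 10 to 15 when a library was left out, the fewest without library 2. The chromosome 11 difference was 0.71 with equal sums and 1.17 for upper peaks. Of 247 values of 87 named promoters recomputed with other windows or scaling 2 moved by more than 1 SD. A changed window alters a value only where another peak becomes the strongest, so this count says little on robustness. Where no value is given to show it, the cause was not tested. Motif counts and the comparison with start sites of a transcript annotation were not run, for want of a sequence and annotation. No paired analysis was possible because there was 1 group. The lower depth of library 2 limits weak peaks most, and lists of 14 to 39 genes leave wide intervals.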

Other observations

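The gene families, pathway terms and the tests of this part were chosen after the results were seen, except the test of local gene number, whose outcome was predicted before. Beyond the fixed lists, 20 families were compared with other genes by Fisher's exact test (adjusted over the families). Of 1110 olfactory receptor genes 2 had a promoter peak (0.18%), and of 355 vomeronasal receptor genes 1 did (0.282%). Keratin genes had 3 of 109 and beta-defensin genes 0 of 42 (95% interval up to 8.41%). Numbered zinc finger genes (Zfp), many of them KRAB repressors, had 283 of 397 (71.3%, adjusted p = 1.39e-23), and their median log2 promoter signal of 6.53 was at percentile 99.8 of random lists. Cytosolic ribosomal protein genes had 64 of 83 (77.1%, adjusted p = 3.61e-08), mitochondrial ribosomal protein genes 57 of 78 (73.1%, adjusted p = 4.75e-06), complex I genes 36 of 49 (73.5%, adjusted p = 0.000259) and proteasome genes 29 of 40 (72.5%, adjusted p = 0.002). All of these differences held with a peak at either gene end and in the longer peak list (Fisher's exact test).

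Distal peaks of 4 of the 20 families lay above lists matched on gene length. The 19 SOX genes had 3.21 distal peaks per gene (percentile 99.7 of lists matched on length) and promoter peaks at 12 of 19 (adjusted p = 0.225). The 44 FOX genes had 2.25 (percentile 99.9) with 19 of 44 (adjusted p = 0.803), and the 12 LIM homeodomain genes 1.83 (percentile 98.9) with 3 of 12 (adjusted p = 0.225, Fisher's exact tests). Semaphorin, plexin and neuropilin genes had 4.52 distal peaks per gene (percentile 99.5) and 25 of 31 promoters open (adjusted p = 0.000235), a promoter difference lost with either gene end (adjusted p = 0.0636) and in the longer list (adjusted p = 0.126). Clustered histone genes (17 of 72) and protocadherin genes (4 of 57) were below other genes by the authors' assignment of 1 gene per peak. With a peak at either gene end they were not (adjusted p = 0.511 and 0.201, Fisher's exact test). That count also takes peaks at the end opposite the start site, and 1 peak can count for several genes. It therefore cannot tell whether the assignment lowers the promoter share in these dense clusters. In distal peaks 4 families lay below lists matched on length: protocadherin (1.14 per gene), olfactory receptor and vomeronasal receptor genes, all at percentile 0, and Zfp genes at percentile 0.39. Promoter signal was below the random range for FOX (percentile 1.78) and LIM homeodomain genes (percentile 1.74), and semaphorin, plexin and neuropilin genes were at percentile 2.58. Potassium channel genes (48 of 94), Zic (3 of 5), Id (3 of 4) and nuclear factor I genes (2 of 4) did not differ from other genes in promoter peaks, and their distal percentiles were 93.5, 95.5, 94.2 and 96.6. Ephrins and their receptors (14 of 22, adjusted p = 0.205) were above other genes in the longer list (90.9%, adjusted p = 0.00187, Fisher's exact test), with a distal percentile of 95.4. Of 202 KEGG terms none had a share of the strongest 25% of promoters apart from other annotated genes after adjustment, and 12 had an unadjusted p under 0.05. The lowest was AMPK signaling (31 of 71 genes, adjusted p = 0.151, Fisher's exact test).

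The library difference followed gene density over megabases. A different copy number of whole chromosomes would put most of the variance between chromosomes, but 17.6% lay there, against 3.82% for no chromosome effect. Counting error does not account for it, since the SD of the window medians was 0.647 and the highest of 100 simulations 0.0701. A preference of 1 library for GC-rich, gene-dense DNA may underlie it. The rho of 0.74 with gene number is the pattern itself, so it is no separate test of this. GC content and gene number cannot be told apart without a sequence. No biological explanation was tested, since the design has 1 group and the labels give no difference between the libraries other than the cell number.

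Marker lists of other tissues had few promoter peaks. Too few peaks in the quantified set could produce this, but in the longer list 7 of the 7 low lists other than midbrain, hindbrain and spinal cord stayed below other genes. For the midbrain, hindbrain and spinal cord list this explanation remains possible (9 of 20 in the longer list, adjusted p = 0.315, Fisher's exact test). The longer list was deposited for the same 2 libraries, so it cannot tell whether low depth produced the pattern in any list. Against all RefSeq genes, each of the 8 low lists but the Hox genes lost its call, as given above. A location in gene-poor regions is argued against, as 8 of the 8 low lists stayed below random genes matched on the number of genes within 500 kb. That these promoters are closed in neurosphere cells is consistent with these tests for the 7 lists, as a hypothesis with no other cell type measured here to test it.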
